A study of Mus musculus with 9 samples.

How the data were processed

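The deposited matrices hold counts of unique molecular identifiers (UMIs) per gene and barcode, with hashtag antibody counts in the same files, per the file headers. Per the labels, libraries were made with the 10x 5' v2 kit from cells digested with Liberase TL and DNase, with viability above 87%, stained with TotalSeq-C hashtags 001 to 004, and the submitters' notes name Cell Ranger 6.0.1, Seurat 4.1.0 and the mm10 build. The file headers of the CD4 deposits name a later Cell Ranger release. Node libraries list 32285 genes and CD4 deposits 33696, of which 32158 of the 32285 were placed with the GENCODE vM21 annotation.

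Barcodes with fewer than 300 genes or more than 10% mitochondrial UMIs were removed. Doublets were called with Scrublet at an assumed rate of 0.06. Its automatic threshold called under 0.5% of cells in dCLN WT and in both CD4 deposits. There, cells with scores above the bound of the highest 5% were removed, 380 in dCLN WT and 315 and 356 in the CD4 deposits. Before this removal, Scrublet had marked 16.8% to 40.8% of the cells that carried more than 1 hashtag. Among the cells left after it, 3.77% to 5.45% still carried more than 1 hashtag. Cells without exactly 1 hashtag were removed for the tests by tube and kept otherwise. Node and mixed libraries were clustered together on log-normalised counts (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1), and clusters were named from marker lists written before the data were examined. Clusters with markers of 2 lineages, or of none clearly, were left unnamed and out of the class sums. So were clusters of 1 lineage whose 10 leading genes held more markers of another class, such as a B cluster of 2050 cells. Unnamed cells made up 21.3% and 15.7% of dCLN, 17.0% and 13.8% of sCLN and 13.7% and 12.0% of iLN, WT before 5xFAD. They stayed in the totals from which shares were taken.

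Counts were summed over the cells of a class within each library, with at least 20 cells. Genes were filtered with filterByExpr, normalised by TMM and tested with edgeR quasi-likelihood F-tests. Node and genotype were fitted together over the 6 libraries, with 2 residual degrees of freedom, so each genotype has 3 libraries, from 3 nodes. The nodes of a genotype may come from the same pooled animals, so these p-values do not measure the spread between animals. P values were adjusted by Benjamini-Hochberg at 0.05. Gene lists, also written before, were tested with camera (limma) at a preset correlation of 0.01 and again with the correlation estimated. Lists needed at least 4 members tested, and p values were adjusted over all list tests together. With the correlation estimated, camera uses only the 2 residual degrees of freedom of the fit, so hardly any list could pass. That version therefore cannot decide whether a list holds. The ribosomal, oxidative phosphorylation and mitochondrial lists were filled by symbol prefix. A list is described only in the classes it concerns. Within 1 node, list medians were set against 10000 random lists of equal size. Shares have exact Clopper-Pearson intervals, which cover counting error only.

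The named-genes rule took, for each contrast, up to 10 genes per direction with the largest log2 fold change among those past the threshold. It asked for at least 50 UMIs over the 6 libraries and for the same direction in all 3 node pairs, or in both genotypes for a contrast of nodes. Where fewer than 5 qualified, the list was filled to 5 by unadjusted p. Variable segment genes of antigen receptors, unnamed genes and mitochondrial genes were counted but not named. Within 1 node it asked for a 1.5-fold change and Poisson intervals that do not overlap. It added App, Thy1, the constant heavy chains and 2 to 4 members per list. Cxcr4, Apoe, Igkc, Gm42418, Cd79a, C1qa and C1qb were named after their values were seen.

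Tube sets were made after the data were seen. Tubes of the 3 nodes were matched within a genotype by the genes that differ between tubes (at least 3-fold, at least 10 CPM). The correlations of matched tubes were 0.906 to 0.991 over 19 genes in WT, where the highest of the other pairs was -0.224. In 5xFAD they were 0.852 to 0.995 over 11 genes, and the highest other pair had 0.507. Tubes were paired to give the highest summed correlation, so matched pairs exceed the others in part by construction. The genes were chosen in dCLN. Between sCLN and iLN, matched pairs had at least 0.942 in WT and 0.982 in 5xFAD, and other pairs at most -0.285 and 0.355. The interferon-induced genes Ifit3 and Ifi213 were among the genes of both genotypes. Usp18 was among those of WT, and Oasl2, Ifi27l2a and Rtp4 were among those of 5xFAD. The match thus rests in part on interferon genes, above all in 5xFAD. Counts were summed per set over nodes and tested 3 against 3.

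The tests were tested on simulated data: 100 genes with a 2-fold change and 100 with a 1.5-fold change were placed into simulated counts. These were drawn from the mean levels, library sizes and dispersions of each class. They held no differences between nodes, tubes or animals, so their false calls do not measure those that such differences bring to the real tests. On libraries, 93 and 75 were found in B-like, 91 and 71 in CD4 T-like and 83 and 69 in CD8 T-like cells, with 15, 20 and 13 false calls. On tube sets 83 and 55, 73 and 54 and 84 and 52 were found, with 10, 7 and 11 false calls. Over all cells 81 and 67 were found on libraries with 20 false calls, and 60 and 25 on tube sets with 4. Software was Python 3.11.15, scanpy 1.11.5, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, leidenalg 0.10.2, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.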

Results

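Cells of 3 lymph nodes were profiled by droplet RNA sequencing from the 5' end of transcripts in female mice aged 10 to 11 months. Deep cervical nodes (dCLN) and superficial cervical nodes (sCLN) drain the head and neck, and inguinal nodes (iLN) drain the skin of the flank and hindlimb, away from the brain. The mice were wild type (WT) or 5xFAD, a line that carries human transgenes, APP among them, with familial Alzheimer's disease mutations and deposits amyloid in the brain. Each of the 6 pairings of node and genotype had 1 library, and 1 further library mixed the nodes and both genotypes. A pair of dCLN libraries was titled CD4. In every library the cells came from 3 or 4 tubes, each marked by its own hashtag antibody, and the labels do not say which animal went into which tube.

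The libraries held between 6537 and 11265 barcodes. Over the 6 node libraries the total was 33406478 UMIs for dCLN WT, 52309334 for dCLN 5xFAD, 38165711 for sCLN WT, 38337067 for sCLN 5xFAD, 31503671 for iLN WT and 36944039 for iLN 5xFAD. The mixed library had 30142936 UMIs and the CD4 libraries 32989453 and 33047006. After filtering, 7859, 10298, 7437, 6931, 6128 and 7665 cells remained in the 6 node libraries in that order, with a median of 3423 to 4648 UMIs per cell. The transcript Gm42418, which overlaps a ribosomal RNA repeat and tracks carry-over of ribosomal RNA, took 2.73% of UMIs in dCLN WT and 1.52% in dCLN 5xFAD.

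Lymph nodes hold mostly B cells and T cells, and the balance between them differed between the libraries of the genotypes. B-like cells made up 42.0% of cells in dCLN WT (95% Clopper-Pearson interval 40.9 to 43.1) and 27.9% in dCLN 5xFAD (27.1 to 28.8). In sCLN the B-like shares were 41.2% (40.1 to 42.4) and 28.6% (27.5 to 29.7), and in iLN 34.2% (33.0 to 35.4) and 25.05% (24.08 to 26.03). CD4 T-like cells went the other way, from 10.4% in WT to 21.96% in 5xFAD in dCLN, from 11.2% to 21.7% in sCLN and from 19.0% to 25.8% in iLN. CD8 T-like cells likewise made up 11.1% and 22.8%, 14.5% and 24.8%, and 20.8% and 29.0%. The mean difference between genotypes over the 3 nodes was -11.9 percentage points (SD 2.51) for B-like cells. It was 9.63 (SD 2.53) for CD4 T-like and 10.1 (SD 1.70) for CD8 T-like cells. A B-like cluster with a median of 1850 UMIs held 990 cells of dCLN WT and 333 of dCLN 5xFAD. It held 467 and 211 in sCLN and 283 and 326 in iLN. Cells below 1500 UMIs numbered 1270 in dCLN WT and 477 in dCLN 5xFAD. Depth thus differed between the dCLN libraries, which bears on their B-like shares and gene contrasts. Smaller classes had lower shares in 5xFAD in all 3 nodes: γδ or type 3 T-like cells by -0.874 percentage points, germinal centre B-like cells by -0.708, regulatory T-like cells by -0.954, migratory dendritic cells by -0.622 and monocytes or macrophages by -0.468 on average. The regulatory T-like shares of dCLN were 5.90% and 5.66%, and that difference turned positive (0.129) with doublets kept. With 3 nodes the exact sign-flip test, 2-sided, gave p = 0.25 for each of these classes, the smallest p that 3 nodes allow. By hashtag tube the picture was less even. The B-like share was 34.0%, 24.9% and 23.8% in the 3 matched tube sets of 5xFAD and 25.5%, 51.3% and 40.9% in those of WT (exact permutation p = 0.2 for 3 against 3, with 0.1 the smallest possible), so 1 WT set lay within the 5xFAD range. CD4 T-like cells made up 20.8%, 24.3% and 24.9% of the 5xFAD sets and 25.03%, 7.21% and 7.97% of the WT sets (exact permutation p = 0.4), so WT set 1 lay above all 5xFAD sets. For CD8 T-like cells the shares were 24.3%, 24.4% and 27.5% against 24.8%, 9.99% and 11.8% (exact permutation p = 0.3). Among the smaller classes the exact permutation p was 0.1 for γδ or type 3 T-like and migratory dendritic cells, 0.2 for germinal centre B-like, 0.3 for regulatory T-like cells and 0.8 for monocytes or macrophages.

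**Figure D1:**
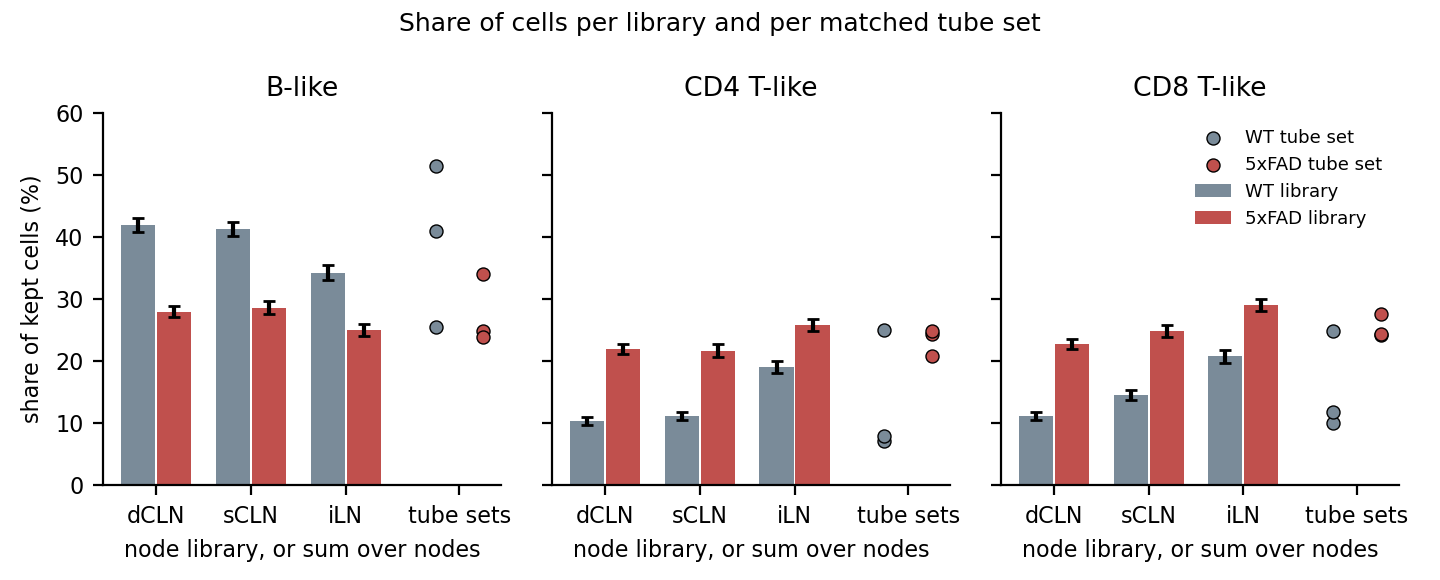
Bars give the share of kept cells (y axis, percent) that were B-like, CD4 T-like or CD8 T-like in each node's WT and 5xFAD library (x axis) with 95% Clopper-Pearson intervals, and points give matched tube sets summed over the nodes. B-like cells fill 42.0% of dCLN WT and 27.9% of dCLN 5xFAD, and 25.5% to 51.3% of the WT tube sets.

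The central question was which genes differ between 5xFAD and WT in each kind of lymphocyte once the node is taken into account. Genes of the response to interferons, the antiviral and antibacterial cytokines, were among those that fell in 5xFAD: 17, 12 and 19 of 25 type I interferon genes in B-like, CD4 T-like and CD8 T-like cells. These lists were not called with an estimated correlation (camera). By matched tube set the type I medians were -0.35, -0.23 and -0.24, and they were -0.20, -0.09 and -0.11 without 5xFAD set 3 and -0.68, -0.50 and -0.40 without 5xFAD set 1. Of 153 genes that passed in the same direction in all 3 classes, 10 also differed between tube sets of 1 genotype. For instance Coro2a, an actin-binding coronin, had 0.705 CPM over all cells in WT tube set 1 but 21.60 and 18.05 CPM in the other sets, and its 5xFAD sets had 1.20, 1.19 and 0.257 CPM. Likewise Ftl1-ps1, a ferritin pseudogene, had 10.95 CPM in 5xFAD set 1, 10.11 and 11.39 CPM in WT sets 1 and 2 and 541 to 565 CPM in the remaining 3 sets. The tests on libraries counted 1156 genes in B-like, 617 in CD4 T-like and 894 in CD8 T-like cells. With matched tube sets as replicates, 3 against 3, the edgeR quasi-likelihood test called 42, 50 and 55 genes, of which 31, 34 and 34 were shared with the library counts, and this alternative was chosen after seeing the data. Of 312 gene list tests 129 were called by camera with its preset correlation, and 0 with an estimated one. The estimated version rests on 2 residual degrees of freedom and could hardly call any list, so it cannot decide between them. The tube sets were matched across nodes by expression alone, so whether each set is 1 animal is an inference.

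**Figure D2:**
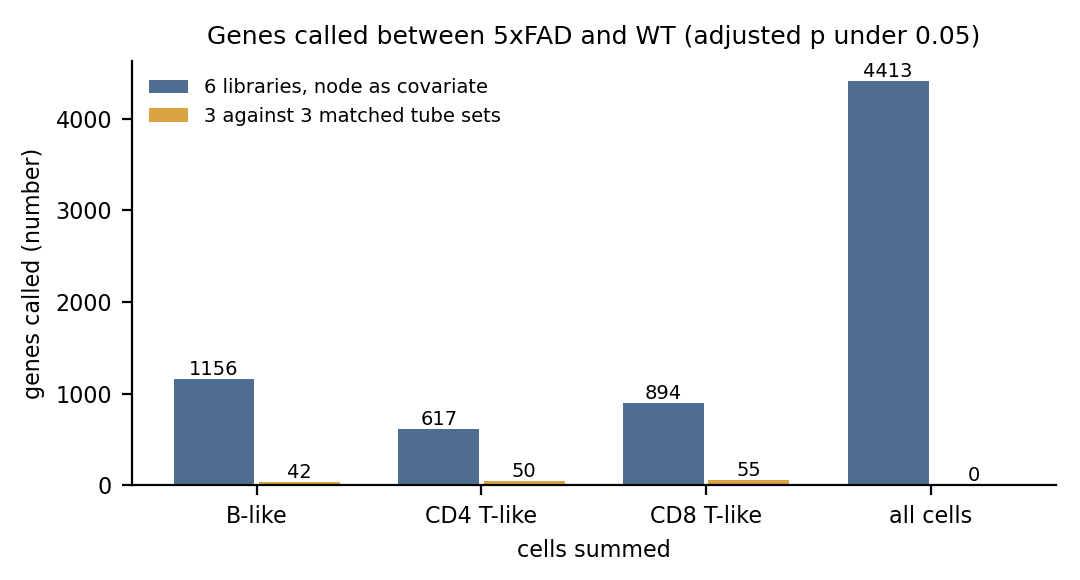
Bars give the number of genes called between 5xFAD and WT by edgeR (y axis, genes) for the cells summed in each class and for all cells (x axis), with the 6 libraries or the matched tube sets, 3 against 3, as replicates. B-like cells have 1156 genes by library and 42 by tube set.

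B cells in the lymph node recirculate through follicles, and interferon sets how they respond to innate signals. In B-like cells of 5xFAD the interferon-induced genes Rsad2, Iigp1, Ifit3 and Isg15 fell, as did the immunoglobulin genes Ighd and Ighm. Cnr1, the cannabinoid receptor, and Nlrp1a, an inflammasome sensor, rose. Of 11001 genes tested over the 6 libraries, 449 rose and 707 fell. Without the dCLN pair 470 genes passed, and without the iLN pair 553.

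Jchain, which joins antibody units in plasma cells, fell by -2.78 ± 0.30 log2 units (SE; edgeR quasi-likelihood, adjusted p = 5.16e-05) and was also called with matched tube sets (adjusted p = 0.00311, edgeR). It lies on chromosome 5 (ENSMUSG00000067149, 88519809 to 88527891, mm10) and had 24.0 CPM in dCLN WT against 4.72 CPM in dCLN 5xFAD, and 15.8 against 0.682 CPM in sCLN. In iLN the values were low in both genotypes, 0.412 CPM in WT and 0.331 CPM in 5xFAD. CD4 T-like cells of dCLN had 17.7 and 3.73 CPM of it and CD8 T-like cells 10.4 and 16.8, so RNA of plasma cells is an alternative source in B-like cells too. Among the 20 genes that the named-genes rule gave, Jchain was the 1 still called by tube set. Coro2a (ENSMUSG00000028337, chromosome 4, 46536937 to 46602202) fell by -5.70 ± 0.27 and had 14.8 CPM in dCLN WT against 0.101 CPM in dCLN 5xFAD. The cilia-related genes Whrn (-5.24 ± 0.40) and Ccdc180 (-4.63 ± 0.51) fell in the same way, and Jhy had 6.09, 6.47 and 7.56 CPM in the WT nodes and was listed at 0 in all 3 5xFAD nodes. Further genes that fell were Sfn (-2.25), Mtus2 (-2.17), Iigp1 (-2.10 ± 0.50), Ighg1 (-1.80 ± 0.49) and Rsad2 (-1.74 ± 0.34). Those that rose most were Nlrp1a (1.68 ± 0.27), Cnr1 (1.47 ± 0.19), Scn8a (1.45), Hspa12a (1.44), Grb7 (1.27), Bcl2a1a (1.23), Sh2b2 (1.13 ± 0.12), Plppr2 (1.11), Fhit (1.08) and Lilrb4a (1.06). Sh2b2, an adaptor of receptor signalling, had 10.5 and 23.2 CPM in dCLN, 11.1 and 22.7 in sCLN and 7.97 and 19.0 in iLN, WT before 5xFAD.

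Of 25 type I interferon genes, 2 rose, 17 fell and 6 did not pass, with a median of -0.35 log2 units (camera adjusted p = 3.3e-15, and 0.453 with an estimated correlation), and adjusted over the list alone 2 rose and 19 fell. Ifit3 fell by -1.26 ± 0.14, Slfn1 by -1.21 and Isg15 by -0.96 ± 0.12. Of 17 interferon-γ genes 11 fell and 6 did not pass (median -0.37, camera adjusted p = 1.75e-12, and 0.453 with an estimated correlation), and adjusted over the list alone 16 fell, among them Gbp6 (-0.96), Irgm2 (-0.80) and Socs1 (-0.79 ± 0.11). MHC class I genes, which present peptides to CD8 T cells, had 1 up, 7 down and 5 not passing of 13 (camera adjusted p = 2.32e-06, and 0.576 with an estimated correlation). It had 1 up and 9 down adjusted over the list alone. Nlrc5, their transactivator, fell by -0.57 and H2-D1 by -0.49. NF-κB targets went the other way, with 4 of 16 up, 0 down and 12 not passing (camera adjusted p = 0.00769, and 0.595 with an estimated correlation), and adjusted over the list alone 7 rose and 1 fell; Ebi3 rose by 0.33 and Nfkb2 by 0.30. Ribosomal protein genes had 18 of 83 down, 1 up and 64 not passing (median -0.10, camera adjusted p = 4.56e-11, and 0.705 with an estimated correlation). It had 28 down and 1 up adjusted over the list alone. Of 12 plasma cell genes 1 rose, 3 fell and 8 did not pass (camera adjusted p = 0.0404, and 0.661 with an estimated correlation), with 1 up and 4 down adjusted over the list alone, and without immunoglobulin genes the list was not called (camera adjusted p = 0.355). Of 11 MHC class II genes 1 rose, 3 fell and 7 did not pass (camera adjusted p = 0.0364, and 0.595 with an estimated correlation), with 1 up and 5 down adjusted over the list alone; H2-DMb1 fell by -0.44 and H2-DMb2 rose by 0.18. Outside the lists, Ighd fell by -0.49 ± 0.05, Ighm by -0.34 ± 0.05, Igkc by -0.28 ± 0.05 and the homing receptor Cxcr4 by -0.69 ± 0.07, while the lipid carrier Apoe rose by 0.38 ± 0.05.

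CD4 T cells are the helper cells that react to antigen drained from tissues, and they pass from a naive to an effector-memory state once they have met it. In CD4 T-like cells of 5xFAD 9 of 19 genes of that state fell, among them Ccl5, S100a6 and Maf, and 9 of 13 regulatory T cell genes, such as Il2ra and Ikzf2. Both lists were not called with an estimated correlation (camera, 0.453). The make-up of the class differed as well. At Leiden resolution 2.0 a CD4 T-like cluster led by S100a4, S100a6 and Maf held a lower share of the class in 5xFAD. In dCLN it held 90 of 965 cells in WT (9.33%) and 153 of 2513 in 5xFAD (6.09%). In sCLN these were 147 of 1011 (14.5%) and 127 of 1682 (7.55%), and in iLN 150 of 1331 (11.3%) and 149 of 2220 (6.71%). Class sums cannot tell such a shift in make-up from a change within cells. Of 10707 genes tested over the 6 libraries, 249 rose and 368 fell. Without the sCLN pair 266 genes passed, and without the iLN pair 376.

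Klrd1, an inhibitory receptor of cytotoxic cells, rose by 1.42 ± 0.12 log2 units (SE; edgeR quasi-likelihood, adjusted p = 1.06e-11) and was also called by tube set (adjusted p = 0.0378, edgeR). Jchain fell by -2.62 ± 0.30 although T cells do not make it, so RNA of other cells is an alternative source, and Rpgrip1 (ENSMUSG00000057132, chromosome 14, 52110704 to 52163546) fell by -2.33 ± 0.30 from 6.72 to 1.28 CPM in dCLN. These 3 genes and Fosb (-2.16 ± 0.32) and Ppp1r3e (-1.94 ± 0.34) were the 5 of 20 named genes still called by tube set. Ifitm3 (ENSMUSG00000025492, chromosome 7, 141009586 to 141010770), which blocks virus entry, fell by -2.50 ± 0.31, from 9.17 to 1.57 CPM in dCLN. Other genes that fell were Spata7 (-2.21), Serpina3g (-2.18), Fcmr (-2.12), Fcer1g (-2.10) and Iglc2 (-1.82). Among those that rose, Cpne4 (ENSMUSG00000032564, chromosome 9, 104547286 to 105034544) changed by 2.03 ± 0.16 and Ftl1-ps1 by 2.00 ± 0.05, both on or off by tube set. Abhd12b (2.17), Hebp1 (1.79), Pianp (1.68), Myo10 (1.53), Vcl (1.48), Dhdh (1.39) and Fam174b (1.22) rose as well.

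Of 19 effector-memory genes 1 rose, 9 fell and 9 did not pass (median -0.44, camera adjusted p = 2.4e-23, and 0.453 with an estimated correlation), and adjusted over the list alone 1 rose and 14 fell. Ccl5, a chemokine of memory cells, fell by -1.67 ± 0.10, S100a6 by -1.15 ± 0.06 and Maf by -1.13. Regulatory T cell genes had 9 of 13 down and 4 not passing (median -0.78, camera adjusted p = 4.39e-09, and 0.453 with an estimated correlation), with 10 down adjusted over the list alone, and Itgae fell by -1.56, Il2ra by -1.13 and Ikzf2 by -0.94. Of 25 type I interferon genes 12 fell and 13 did not pass (median -0.34, camera adjusted p = 1.4e-11, and 0.595 with an estimated correlation), with 14 down adjusted over the list alone, such as Oas1a (-0.72) and Oasl2 (-0.71). Of 17 interferon-γ genes 5 fell and 12 did not pass (camera adjusted p = 2.36e-06, and 0.594 with an estimated correlation), with 7 down adjusted over the list alone; Gbp8 fell by -0.85. Type 1 and cytotoxic genes had 5 down, 1 up and 4 not passing of 10 (camera adjusted p = 2.05e-05, and 0.486 with an estimated correlation), with 6 down and 1 up adjusted over the list alone, and this list was not called by tube set (camera adjusted p = 0.685). Klrg1 fell by -2.47 and Nkg7 by -1.30 in that list. Exhaustion genes had 3 of 8 down and 5 not passing (camera adjusted p = 0.000339, and 0.453 with an estimated correlation), 6 down adjusted over the list alone, with Lag3 at -2.91 and Ctla4 at -0.64. Of 5 type 2 and type 3 genes 3 fell and 2 did not pass (camera adjusted p = 0.00163, and 0.46 with an estimated correlation), also 3 down adjusted over the list alone, with Ccr6 at -1.18. Homing receptor genes had 1 up, 5 down and 10 not passing of 16 (camera adjusted p = 0.00181, and 0.576 with an estimated correlation). It had 2 up and 8 down adjusted over the list alone. Immediate early genes, which respond within minutes to activation or handling, had 1 up, 7 down and 12 not passing of 20 (camera adjusted p = 0.00171, and 0.616 with an estimated correlation), with 2 up and 7 down adjusted over the list alone, and were not called by tube set (camera adjusted p = 0.465); Egr3 fell by -2.13 and Jun by -0.82. Genes of oxidative phosphorylation had 4 of 82 down and 78 not passing (camera adjusted p = 0.000586, and 0.71 with an estimated correlation). It had 3 down adjusted over the list alone. Ribosomal protein genes had 9 of 83 down, 1 up and 73 not passing (camera adjusted p = 0.000652, and 0.804 with an estimated correlation), the same counts adjusted over the list alone. MHC class II genes had 3 of 9 down and 6 not passing (camera adjusted p = 1.11e-06, and 0.595 with an estimated correlation), 5 down adjusted over the list alone, beside the B cell gene Cd79a at -1.43 ± 0.23, so RNA of B cells is an alternative source of this change.

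CD8 T cells read MHC class I on other cells and kill infected ones. In those of 5xFAD the interferon-induced genes Isg15, Ifit3 and Rsad2 fell, as did Ccl5, the memory-cell chemokine. Of 10952 genes tested over the 6 libraries, 336 rose and 558 fell. Without the dCLN pair 548 genes passed, and without the iLN pair 567.

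Rpgrip1 fell by -2.42 ± 0.18 log2 units (SE; edgeR quasi-likelihood, adjusted p = 4.53e-17), from 14.2 to 1.97 CPM in dCLN, 12.6 to 3.23 in sCLN and 13.0 to 2.25 in iLN. It was called by tube set too (adjusted p = 4.79e-05, edgeR), as was Ppp1r3e, a glycogen phosphatase subunit (-2.12 ± 0.31; adjusted p = 0.00435, edgeR), and no other of the 20 named genes. Coro2a (-3.16), Ifitm3 (-2.59 ± 0.42), Tspan9 (-2.16), Napsa (-1.90), Tcrg-C4 (-1.88), Ly6d (-1.86), Trib3 (-1.77) and Luzp1 (-1.68) fell in the library test. Pcsk1 (2.22 ± 0.44), Hist1h4m (1.79), Pianp (1.73), Xlr3b (1.60), Cpne4 (1.503 ± 0.107), Ftl1-ps1 (1.45 ± 0.05), Pdlim4 (1.34), Lmtk3 (1.29), Dhdh (1.25) and Vcl (1.10) rose.

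Of 25 type I interferon genes 19 fell and 6 did not pass (median -0.35, camera adjusted p = 9.88e-29, and 0.453 with an estimated correlation). It had 21 down adjusted over the list alone. Rsad2 fell by -1.59, Ifit3 by -1.27 and Isg15 by -0.93 ± 0.06. Of 18 interferon-γ genes 10 fell, 1 rose and 7 did not pass (camera adjusted p = 1.38e-09, and 0.483 with an estimated correlation), with 14 down and 1 up adjusted over the list alone, the chemokine Cxcl10 falling by -2.30 and Gbp8 by -0.77. Ribosomal protein genes had 42 of 83 down and 41 not passing (camera adjusted p = 3.64e-25, and 0.595 with an estimated correlation). It had 60 down adjusted over the list alone. Genes of oxidative phosphorylation had 21 of 82 down and 61 not passing (median -0.08, camera adjusted p = 2.95e-08, and 0.654 with an estimated correlation). It had 29 down and 2 up adjusted over the list alone. Type 1 and cytotoxic genes had 4 of 12 down and 8 not passing (camera adjusted p = 2.92e-05, and 0.453 with an estimated correlation), 6 down adjusted over the list alone: Ccl5 fell by -1.55 ± 0.09, Cxcr3 by -0.51 and Eomes by -0.40. MHC class I genes had 6 of 13 down and 7 not passing (camera adjusted p = 0.000273, and 0.453 with an estimated correlation). It had 7 down and 1 up adjusted over the list alone. Regulatory T cell genes had 5 of 11 down and 6 not passing (camera adjusted p = 5.87e-05, and 0.453 with an estimated correlation), and exhaustion genes 2 of 10 down and 8 not passing (camera adjusted p = 0.0129, and 0.545 with an estimated correlation). They had 5 and 3 down adjusted over the list alone. Mitochondrially encoded genes had 3 of 13 down, 1 up and 9 not passing (camera adjusted p = 0.0176, and 0.709 with an estimated correlation). It had 7 down and 1 up adjusted over the list alone. MHC class II genes had 5 of 11 down and 6 not passing (camera adjusted p = 1.66e-07, and 0.453 with an estimated correlation), 6 down adjusted over the list alone, beside Cd79a at -1.60 ± 0.18, as in CD4 T-like cells.

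**Figure D3:**
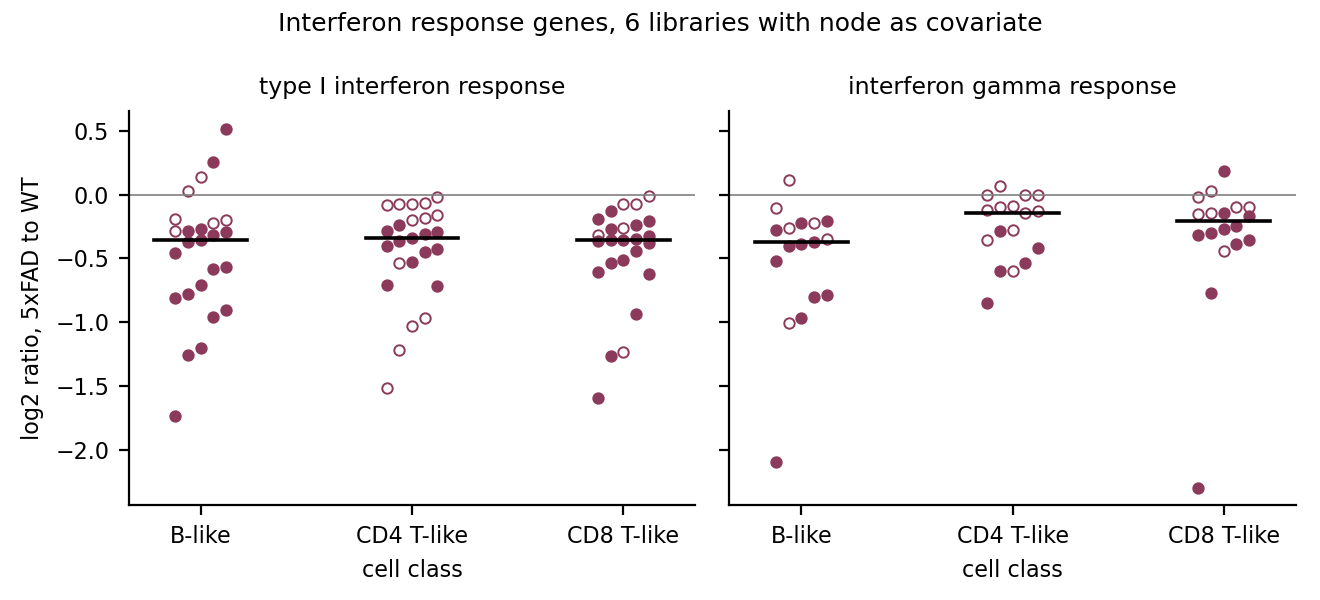
Each point is 1 gene of the type I interferon or interferon-γ list, with its log2 ratio of 5xFAD to WT (y axis, log2 units) by cell class (x axis); filled points passed the edgeR test and black lines are medians. The type I medians are -0.35, -0.34 and -0.35 in B-like, CD4 T-like and CD8 T-like cells.

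Summed over all cells, differences in expression mix with the differences in class shares, and 10 of 14 naive T cell genes rose while 10 of 13 germinal centre genes fell, both lists not called with an estimated correlation (camera). Of 14448 genes tested, 1985 rose and 2428 fell, and without the dCLN pair 2906 genes passed and without the sCLN pair 2743. With matched tube sets the edgeR quasi-likelihood test called 0 genes (2074 at an unadjusted p under 0.05), and DESeq2 called 1926 on the libraries. Neutrophil granule genes Ngp (-5.04 ± 0.56) and Lcn2 (-3.30 ± 0.62), the chemokines Cxcl2 (-3.86) and Ccl7 (-3.37), Serpinb2 (-3.78), Il12b (-3.14), Ccdc180 (-5.11) and Coro2a (-3.91) fell. Jhy had 3.18, 2.59 and 2.22 CPM in the WT nodes and at most 0.0277 CPM in 5xFAD, and the water channel Aqp1 had 5.34 CPM in dCLN WT and 0.612 CPM in dCLN 5xFAD. Endothelium-like cells were 1.05% of dCLN cells in WT tube set 1 and 0 in the other WT sets. Pcsk1 (2.16), Abhd12b (1.77), Tom1l1 (1.61), Hist1h4m (1.53), Zfp503 (1.503), Nlrp1a (1.33 ± 0.12), Echdc2 (1.27), Enthd1 (1.23), Acpp (1.16 ± 0.07) and Peli3 (1.13) rose.

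In the same sums, naive T cell genes had 10 of 14 up and 4 not passing (median 0.46, camera adjusted p = 1.12e-07, and 0.563 with an estimated correlation), 11 up adjusted over the list alone, in step with the larger T-like share. All 11 MHC class II genes fell (median -0.52, camera adjusted p = 1.24e-12, and 0.553 with an estimated correlation). It had 11 down adjusted over the list alone. Age-associated B cell genes had 12 of 15 down and 3 not passing (camera adjusted p = 3e-09, and 0.453 with an estimated correlation), and germinal centre genes 10 of 13 down and 3 not passing (camera adjusted p = 1.12e-05, and 0.628 with an estimated correlation). They had 12 and 10 down adjusted over the list alone. Cell cycle genes had 11 of 16 down and 5 not passing (camera adjusted p = 7.13e-06, and 0.643 with an estimated correlation), and myeloid genes 4 of 8 down and 4 not passing (camera adjusted p = 1.77e-05, and 0.563 with an estimated correlation). They had 12 and 4 down adjusted over the list alone. Effector-memory genes had 12 of 19 down and 7 not passing (camera adjusted p = 3.12e-06, and 0.453 with an estimated correlation), regulatory T cell genes 10 of 14 down and 4 not passing (camera adjusted p = 1.77e-05, and 0.546 with an estimated correlation), and plasma cell genes 8 of 14 down and 6 not passing (camera adjusted p = 0.000128, and 0.616 with an estimated correlation). They had 13, 11 and 9 down adjusted over the list alone. Exhaustion genes had 1 up, 9 down and 5 not passing of 15, follicular helper genes 1 up, 8 down and 4 not passing of 13, and type 2 and type 3 genes 1 up, 5 down and 5 not passing of 11, the same counts adjusted over the list alone; the 3 lists had 0.453, 0.663 and 0.595 with an estimated correlation (camera). NF-κB targets had 10 of 16 down and 6 not passing, and erythroid genes 5 of 6 down and 1 not passing, with 11 down and 1 up and with 5 down adjusted over the list alone, and 0.663 and 0.563 with an estimated correlation (camera). Ribosomal protein genes went up, with 12 up, 3 down and 69 not passing of 84 (camera adjusted p = 0.00362, and 0.824 with an estimated correlation). It had 9 up and 2 down adjusted over the list alone. Of 14 genes of the microglia-like disease state, 3 rose, 9 fell and 2 did not pass (camera adjusted p = 0.029, and 0.563 with an estimated correlation), with 4 up and 9 down adjusted over the list alone, and the complement genes C1qa and C1qb changed by -0.74 and -0.96.

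The transgenes could be seen only through mouse sequence, since the reads were aligned to the mouse genome. App rose by 0.47 ± 0.10 log2 units in CD4 T-like cells (edgeR quasi-likelihood, adjusted p = 0.00173; by tube set 0.134) and by 0.44 ± 0.10 in CD8 T-like cells (edgeR adjusted p = 0.00243; by tube set 0.075), and in B-like cells it had -0.38 ± 0.25 and did not pass. Thy1 did not pass in T-like cells. In B-like cells it fell by -0.95 ± 0.25 (edgeR adjusted p = 0.00574; by tube set 0.503), with 12.7 CPM in dCLN WT and 4.12 CPM in dCLN 5xFAD. RNA of T cells is an alternative source there. Gm42418 had -0.64 ± 0.21, -0.45 ± 0.09 and -0.65 ± 0.17 in B-like, CD4 and CD8 T-like cells and did not pass by library (edgeR adjusted p = 0.279, 0.0666 and 0.233), but passed by tube set (edgeR adjusted p = 0.000102, 0.0128 and 0.0012).

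Within single nodes each genotype had 1 library, so no test on libraries was made, and tubes of 1 library share its capture. The type I interferon list was set against 10000 random lists. Its median was -0.29 in dCLN, -0.42 in sCLN and -0.36 in iLN for B-like cells, -0.24, -0.06 and -0.59 for CD4 T-like cells and -0.25, -0.27 and -0.35 for CD8 T-like cells. These were below all random lists except in CD4 T-like cells of sCLN, where 0.55% were lower. Interferon-γ genes had medians of -0.47, -0.22 and -0.18 in B-like, -0.17, 0.06 and -0.41 in CD4 T-like and -0.24, -0.02 and -0.19 in CD8 T-like cells, and the value of sCLN CD4 T-like cells changed sign to -0.00833 with cells thinned to 1500 UMIs, a total that 344 cells of sCLN WT and 242 of sCLN 5xFAD did not reach, these cells being left out. In dCLN B-like cells Ighg2c had 1.13 CPM in 5xFAD against 35.9 in WT, and the antiprotease Slpi 1.03 against 37.2. Ighg2c differed in the same way in dCLN CD4 T-like (0.0995 against 27.1 CPM) and CD8 T-like cells (0.0783 against 19.7 CPM), so RNA of plasma cells is an alternative source. CD4 T-like cells of iLN had 5.02 CPM of Ifit3 in 5xFAD against 46.7 in WT and 29.4 CPM of Isg15 against 110. Over all cells of iLN, Ifit3 had 50.3, 21.5 and 5.47 CPM in the WT tubes and 6.63, 5.35 and 11.7 CPM in those of 5xFAD. Thus 1 WT tube lay within the 5xFAD range. In dCLN it had 5.91, 33.1 and 5.04 CPM in the WT tubes and 22.5, 4.51 and 3.10 CPM in those of 5xFAD. The sCLN values were 17.4, 10.1 and 26.1 CPM in WT and 10.4, 19.7 and 4.65 CPM in 5xFAD. In both cervical nodes the highest 5xFAD tube lay above all WT tubes but the highest. Hbb-bs, a red-cell globin, had 0.669 CPM in 5xFAD and 257 in WT in iLN B-like cells and 7.58 and 232 in CD4 T-like cells, but 183 and 204 in CD8 T-like cells of the same libraries.

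The second question was how the nodes differ, with the genotype as covariate. Of 10 heat shock genes, which encode chaperones, 8, 5 and 7 rose in dCLN against iLN in B-like, CD4 T-like and CD8 T-like cells, and 9, 5 and 7 against sCLN. Of the interferon-γ genes 3 of 17, 4 of 17 and 9 of 18 rose in sCLN against iLN, with 1 down in CD8 T-like cells. These lists were not called with an estimated correlation (camera). Hist1h2ap, Hist2h2aa1, Dynlt1b and Rnaset2a were lower in dCLN in some of the classes, but each has near-identical copies in the genome, so their reads can be shared between copies and their levels are uncertain. Fits on 18 hashtag tubes with the matched tube set as block gave 304, 17 and 150 genes in B-like cells, 314, 17 and 131 in CD4 T-like and 344, 26 and 217 in CD8 T-like cells for dCLN against iLN, sCLN against iLN and dCLN against sCLN. The DESeq2 Wald test on the libraries called 41, 1 and 26 genes in B-like cells for these contrasts, and fewer than edgeR on libraries in the T-like classes too.

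In B-like cells 175 genes rose and 144 fell in dCLN against iLN, 37 and 15 in sCLN against iLN, and 121 and 76 in dCLN against sCLN. The salivary gland proteins Bpifa2 (ENSMUSG00000042459, chromosome 2, 154008265 to 154016079) and Smr3a were found only in sCLN, whose nodes lie by the salivary glands: Bpifa2 had 5.62 CPM in WT and 22.7 in 5xFAD, Smr3a 1.78 and 7.10, and both were at 0 in dCLN and iLN. Counts for dCLN against iLN, 319 in all, were 203 without dCLN WT, 91 without iLN WT and 183 without iLN 5xFAD. For sCLN against iLN 52 became 79 without dCLN WT and 116 without sCLN 5xFAD, and for dCLN against sCLN 197 became 109 without dCLN WT.

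Jchain rose by 5.34 ± 0.54 log2 units in dCLN against iLN and by 4.47 ± 0.60 in sCLN against iLN (edgeR quasi-likelihood, adjusted p = 7.07e-05 and 0.00295), at levels near those of CD4 T-like cells (17.7 CPM in dCLN WT and 0.347 in iLN WT), so RNA of plasma cells is an alternative source. Rgcc (2.87), Cxcl13 (1.79) and Rgs1 (1.69) rose in dCLN against iLN. The T cell genes Themis (2.09), Nkg7 (1.91), Il7r (1.89), Izumo1r (1.73) and Cd28 (1.68) also rose there, and Themis (2.53), Cd28 (2.45), Trbc2 (2.39), Il2rb (2.36), Prkch (2.33), Igfbp4 (2.28), Trac (2.16), Thy1 (2.06), Prkcq (1.97) and Cd3g (1.75) in dCLN against sCLN, so RNA of T cells in the B-like class is an alternative source. Trac had 5.48 CPM in dCLN WT and 1.01 in dCLN 5xFAD, against 0.750 and 0.682 in sCLN. Thy1 had 12.7 and 4.12 against 1.78 and 2.32, so dCLN WT carried much of both values. Styxl1 (-1.63), Fam177a (-1.57), Hist1h2ap (-1.41 ± 0.11), Sag (-1.26), Snhg9 (-1.24) and Commd5 (-1.02) fell in dCLN against iLN. In sCLN against iLN, Zbp1, a sensor of viral nucleic acid (0.66 ± 0.11), Xaf1 (0.58 ± 0.11) and Socs1 (0.72 ± 0.14) rose, as did Serpina3f (0.94), Dusp4 (0.81) and Tgtp2 (0.65). Egr1 (-0.55 ± 0.09), Hist1h2ap (-0.42) and Junb (-0.35 ± 0.06) fell.

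Heat shock genes had 8 of 10 up and 2 not passing in dCLN against iLN (median 0.57, camera adjusted p = 1.46e-42, and 0.453 with an estimated correlation), 8 up adjusted over the list alone, and 9 up and 1 not passing in dCLN against sCLN (median 0.50, camera adjusted p = 3.53e-51, and 0.453 with an estimated correlation). It had 9 up adjusted over the list alone. Hsph1 rose by 1.06 ± 0.09, Dnaja1 by 0.75 and Hspa8 by 0.63 against iLN. Immediate early genes had 8 of 20 up, 1 down and 11 not passing in dCLN against iLN (camera adjusted p = 8.45e-17, and 0.453 with an estimated correlation), 10 up and 1 down adjusted over the list alone, with Fosb (1.62), Dusp1 (1.18) and Fos (0.81) up and Egr1 (-0.52) down; 7 rose and 13 did not pass against sCLN (camera adjusted p = 1.19e-31, and 0.446 with an estimated correlation). It had 11 up adjusted over the list alone. Type I interferon genes had 11 of 25 up and 14 not passing in dCLN against iLN (camera adjusted p = 4.22e-15, and 0.453 with an estimated correlation; by tubes 0.162), 14 up adjusted over the list alone, and 7 up and 18 not passing in sCLN against iLN (camera adjusted p = 2.15e-26, and 0.453 with an estimated correlation), 12 up adjusted over the list alone. Interferon-γ genes had 3 of 17 up and 14 not passing in sCLN against iLN (camera adjusted p = 1.93e-13, and 0.453 with an estimated correlation), 10 up adjusted over the list alone, and 2 down and 15 not passing in dCLN against sCLN (camera adjusted p = 0.000373, and 0.553 with an estimated correlation). It had 2 down adjusted over the list alone. NF-κB targets had 4 of 16 up and 12 not passing in dCLN against iLN (camera adjusted p = 0.000901, and 0.58 with an estimated correlation), 5 up adjusted over the list alone, with Cd83 at 0.52. The 5 switched immunoglobulin heavy chain genes did not pass singly in dCLN against iLN, though the list was called (median 1.21, camera adjusted p = 0.00171, and 0.553 with an estimated correlation). It had 3 up adjusted over the list alone. Naive follicular B cell genes had 2 down in dCLN against iLN, Cd55 (-0.31) and Fcer2a (-0.27), with the rest not passing (camera adjusted p = 0.00157, and 0.563 with an estimated correlation). It had 2 down adjusted over the list alone.

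In CD4 T-like cells the chemokine receptor Ccr10, which binds a chemokine of the epidermis, and the integrin Itgae fell in both cervical nodes against iLN. Ccr10 (ENSMUSG00000044052, chromosome 11, 101172997 to 101175443) fell by -2.99 ± 0.34 in dCLN and by -2.04 ± 0.30 in sCLN against iLN (edgeR quasi-likelihood, adjusted p = 2.8e-08 for dCLN), with 11.3 and 8.47 CPM in iLN WT and 5xFAD and at most 2.45 CPM elsewhere. Itgae (ENSMUSG00000005947, chromosome 11, 73090583 to 73147446), which binds epithelial cadherin, fell by -2.19 ± 0.35 and -2.06 ± 0.35. The counts were 110 up and 112 down for dCLN against iLN, 14 and 12 for sCLN against iLN and 39 and 47 for dCLN against sCLN. Of these, 222 in all became 111 without iLN WT. For sCLN against iLN 26 became 48 without dCLN WT, 52 without dCLN 5xFAD and 9 without sCLN WT, and for dCLN against sCLN 86 became 55 without sCLN WT and 22 without sCLN 5xFAD.

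Fos rose by 1.83 ± 0.16 and Jun by 1.80 ± 0.18 in dCLN against iLN (edgeR adjusted p = 5.72e-11 and 1.06e-09), and by 1.36 ± 0.16 and 1.13 ± 0.17 against sCLN. Fosb (2.37), Art2b (1.56), Ifitm3 (1.53) and Nrp1 (1.02) rose against iLN, beside the B cell genes Jchain (5.44), Iglc2 (1.88), Ly6d (1.66) and Cd79a (1.10), and Ccr8 (-2.35), Acat3 (-2.27), Cpd (-1.73), Snhg9 (-1.65) and Il2 (-1.57) fell. Against sCLN, Fcmr (2.39), Ly6d (2.05), Rgs2 (0.91), Lman2l (0.90), Hsph1 (0.80 ± 0.10) and Siah2 (0.75) rose in dCLN, and Nme3 (-1.19), Anxa2 (-1.05), Fam177a (-0.97), Cxcr3 (-0.79), S100a6 (-0.73 ± 0.09), Naa10 (-0.70) and Rnaset2a (-0.70) fell. In sCLN against iLN the interferon-induced genes Irgm2 (0.55), Igtp (0.53 ± 0.08), Gbp2 (0.50 ± 0.09) and Irf1 (0.38 ± 0.06) rose with Dtx1 (0.60) and Socs3 (0.53), while Cd8a (-0.97), Cxcr6 (-0.85), Nkg7 (-0.81), Ccl5 (-0.65), Ahnak (-0.49) and S100a6 (-0.34) fell. The directions of Ccr8 against iLN in dCLN, of S100a6 against sCLN and of Cd8a, Ccl5 and Ahnak in sCLN reversed with doublets kept or with stricter quality limits. Hbb-bs had 233 CPM in iLN WT, 7.57 in iLN 5xFAD and at most 0.0982 CPM in the other nodes.

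Effector-memory genes had 10 of 19 down and 9 not passing in dCLN against iLN (median -0.60, camera adjusted p = 5.36e-36, and 0.446 with an estimated correlation), 15 down adjusted over the list alone, among them Lgals3 (-1.49), Cxcr6 (-1.42) and Ccl5 (-0.86). They had 4 down and 15 not passing in sCLN against iLN (camera adjusted p = 4.58e-12, and 0.453 with an estimated correlation) and 3 down and 16 not passing in dCLN against sCLN (camera adjusted p = 2.14e-15, and 0.453 with an estimated correlation). They had 7 down each adjusted over the list alone. Homing receptor genes had 3 up, 5 down and 8 not passing of 16 in dCLN against iLN (camera adjusted p = 0.00225, and 0.594 with an estimated correlation). It had 5 up and 7 down adjusted over the list alone. In sCLN against iLN the median of this list was 0.06 while the test gave the direction down, with 3 down and 13 not passing (camera adjusted p = 0.0244, and 0.616 with an estimated correlation). It had 1 up and 4 down adjusted over the list alone. Heat shock genes had 5 of 10 up and 5 not passing in dCLN against iLN (median 0.34, camera adjusted p = 2.26e-21, and 0.453 with an estimated correlation) and against sCLN (median 0.35, camera adjusted p = 2.7e-29, and 0.453 with an estimated correlation). They had 7 up each adjusted over the list alone. Immediate early genes had 8 of 20 up and 12 not passing in dCLN against iLN (camera adjusted p = 2.87e-23, and 0.453 with an estimated correlation), 10 up and 1 down adjusted over the list alone, and 6 up and 14 not passing against sCLN (camera adjusted p = 4.2e-17, and 0.458 with an estimated correlation). It had 8 up and 1 down adjusted over the list alone. Interferon-γ genes had 4 of 17 up and 13 not passing in sCLN against iLN (camera adjusted p = 1.23e-21, and 0.453 with an estimated correlation), 9 up adjusted over the list alone, and 3 down and 14 not passing in dCLN against sCLN (camera adjusted p = 2.98e-09, and 0.558 with an estimated correlation). It had 6 down adjusted over the list alone. Type I interferon genes had 2 of 25 up and 23 not passing in sCLN against iLN (camera adjusted p = 1.03e-07, and 0.643 with an estimated correlation). It had 7 up adjusted over the list alone.

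In CD8 T-like cells the memory-cell chemokine Ccl5 rose in both cervical nodes against iLN, by 1.16 ± 0.11 in dCLN (edgeR quasi-likelihood, adjusted p = 2.01e-12) and by 1.09 ± 0.11 in sCLN. The chaperone gene Hsph1 rose in dCLN against sCLN, and the immediate early gene Fos against both other nodes. The counts were 129 up and 135 down for dCLN against iLN, 30 and 13 for sCLN against iLN, and 49 and 83 for dCLN against sCLN. For dCLN against iLN 264 became 158 without dCLN 5xFAD and 104 without iLN WT. For sCLN against iLN 43 became 74 without dCLN WT, 75 without dCLN 5xFAD and 15 without iLN WT, and for dCLN against sCLN 132 became 76 without sCLN 5xFAD.

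Fos (1.68 ± 0.16), Jun (1.32), Crip2 (1.29) and Dtx4 (1.90) rose in dCLN against iLN, beside the B cell genes Ms4a1 (1.70), Cd79a (1.70), Iglc2 (1.68), Ly6d (1.80) and H2-Ab1 (1.67). Cxcl10 fell by -4.43 ± 0.57 in dCLN and by -2.63 in sCLN, and Wnt10a (-2.05), Klrb1a (-2.03) and Snhg9 (-1.76) fell in dCLN. In sCLN against iLN, Dtx4 (1.53), Gbp10 (0.70), Igtp (0.53 ± 0.06), Nt5e (0.50), Irgm2 (0.46) and Rtp4 (0.46) rose and Pus7 (-0.48), Gapdh (-0.27) and Tuba1b (-0.23) fell. In dCLN against sCLN, Fos (1.13), Hsph1 (0.74 ± 0.08), Dusp1 (0.66), Dnajb1 (0.55 ± 0.06), Hsp90aa1 (0.53 ± 0.06), N4bp3 (0.65), Zdhhc9 (0.62), Ahsa2 (0.62) and Slpi (0.56) rose, and Fam177a (-1.38), Rmrp (-1.35), Irf4 (-1.21), Dynlt1b (-1.20), Nme3 (-0.83), Slc20a2 (-0.75), Tgtp1 (-0.72) and Scamp4 (-0.71) fell. Hbb-bs had 204 and 183 CPM in iLN WT and 5xFAD, and all 5 erythroid genes tested fell in dCLN against iLN (camera adjusted p = 2.6e-274, and 0.446 with an estimated correlation), and so did they in sCLN against iLN (0.21 with an estimated correlation); these are red cell transcripts.

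Heat shock genes had 7 of 10 up and 3 not passing in dCLN against iLN (median 0.25, camera adjusted p = 4.36e-19, and 0.453 with an estimated correlation) and against sCLN (median 0.27, camera adjusted p = 1.55e-24, and 0.453 with an estimated correlation). They had 8 up each adjusted over the list alone. Immediate early genes had 7 of 22 up and 15 not passing in dCLN against iLN (camera adjusted p = 1.04e-10, and 0.453 with an estimated correlation) and 5 up and 17 not passing against sCLN (camera adjusted p = 1.21e-12, and 0.453 with an estimated correlation). They had 9 and 12 up adjusted over the list alone. Interferon-γ genes had 9 of 18 up, 1 down and 8 not passing in sCLN against iLN (median 0.31, camera adjusted p = 4.55e-25, and 0.453 with an estimated correlation), 16 up and 1 down adjusted over the list alone, and 5 down and 13 not passing in dCLN against sCLN (camera adjusted p = 3.49e-15, and 0.453 with an estimated correlation). It had 11 down adjusted over the list alone. Type I interferon genes had 4 of 25 up and 21 not passing in sCLN against iLN (camera adjusted p = 8.41e-18, and 0.453 with an estimated correlation), 14 up adjusted over the list alone, and 2 down and 23 not passing in dCLN against sCLN (camera adjusted p = 3.19e-10, and 0.453 with an estimated correlation). It had 9 down adjusted over the list alone.

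**Figure D4:**
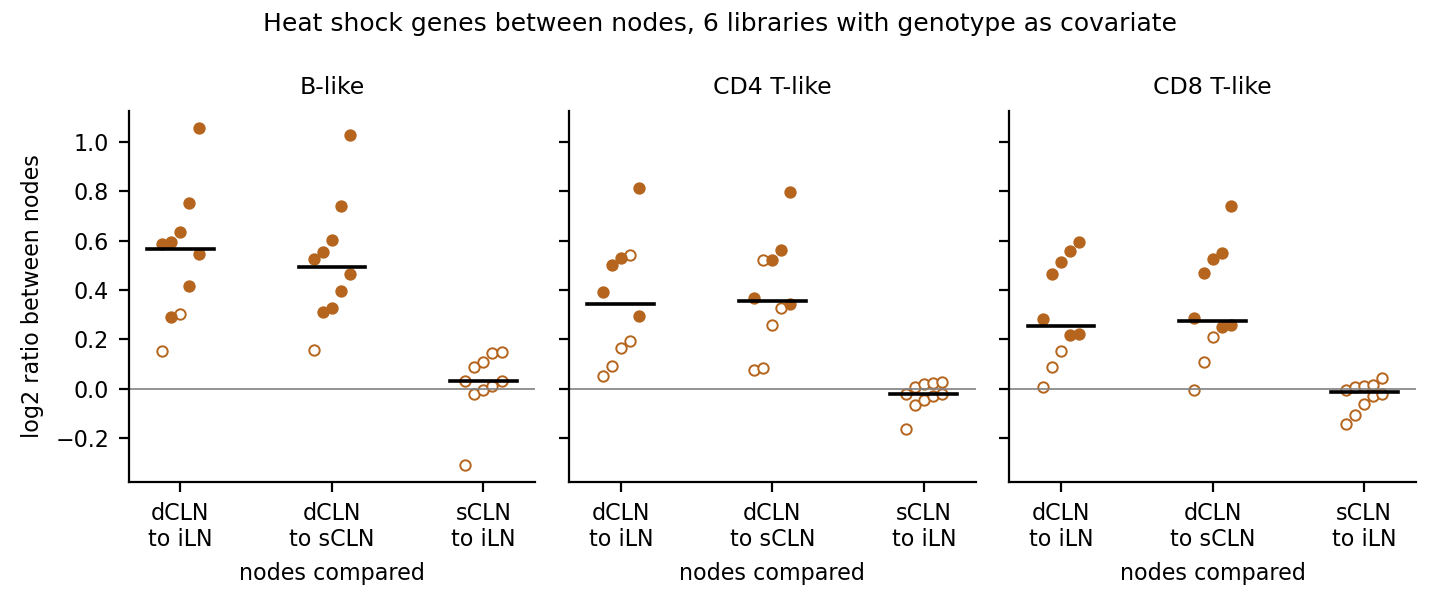
Each point is 1 heat shock gene, with its log2 ratio between nodes (y axis, log2 units) by the nodes compared (x axis) and 1 panel per cell class; filled points passed the edgeR test and black lines are medians. The medians for dCLN against iLN are 0.57, 0.34 and 0.25 in B-like, CD4 T-like and CD8 T-like cells.

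The dCLN libraries titled CD4 address the genotype in CD4 T cells of the node that drains the brain's coverings, but they gave no genotype comparison. They shared 7809 barcodes, 95.1% of the UMIs in shared barcodes were identical and 99.8% of shared cells had the same hashtag, while other pairs of libraries shared at most 150 barcodes. The mean squared difference per gene over its counting variance was 0.116 over 14617 genes, against 60.6, 34.1 and 20.6 for WT against 5xFAD in dCLN, sCLN and iLN. Taken as 1 capture, 72.3% of its cells were CD4 T-like, 14.6% regulatory T-like, 4.49% follicular helper-like, 1.42% γδ or type 3 T-like and 0.523% cycling, as means of the 2 deposits.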

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

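The tests chosen after the result was seen were those on other splits of the samples, on gene positions, on differences within a genotype and by matched tube set; those on interferon and heat shock genes were set before their values were read, although both patterns had been seen.

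The genotype effect differed between nodes in a test of the difference itself, with hashtag tubes as replicates (edgeR quasi-likelihood). In B-like cells 70 genes differed between iLN and sCLN, 23 between dCLN and sCLN and 39 between dCLN and iLN. The same counts were 8, 13 and 29 in CD4 T-like cells, 7, 73 and 32 in CD8 T-like cells and 11, 70 and 36 over all cells. Gclm, which makes glutathione, was among them, with a difference of 1.22 ± 0.11 log2 units between dCLN and iLN in CD8 T-like cells. All tubes of a node and genotype shared 1 capture, so a difference between nodes and a difference between captures cannot be told apart.

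In the CD4 capture, cells of cluster 3, led by the interferon-γ genes Gbp2, Iigp1 and Tgtp1, made up 24.2% of tube 1 against 5.75%, 3.84% and 8.59% of the other tubes. Cluster 5, led by Cnga1, Slc28a2b, Cpne4, Ly6c1 and Klrd1, made up 20.8% of tube 3 against 1.54%, 0.739% and 2.15%. The mixed library held 936 of the 1067 cells of cluster 12, a B-like group with Gm43305, Trim12a and Serpina3f, which was 12.4% of its cells. Gm43305 and Cpne4 also differed between tubes of 1 genotype in the node libraries. Over all cells of dCLN, Gm43305 had 66.0, 200 and 17.1 CPM in the WT tubes. Cpne4 had 0.155, 22.1 and 45.6 CPM in the 5xFAD tubes of dCLN. No biological explanation was tested for these clusters, since the labels give the tubes no group.

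The genes called by genotype were set against other splits of the 6 samples into 3 and 3. In B-like cells the real split called 1156 genes over libraries and the highest other split 12; over matched tube sets these were 42 and 8. CD4 T-like cells had 617 and 16, and 50 and 9, and CD8 T-like cells 894 and 20, and 55 and 22. All cells had 4413 and 2 over libraries, and 0 and 3 over tube sets, where all 10 splits called at least as many (0 genes by edgeR, 2074 at an unadjusted p under 0.05, and 1926 by DESeq2 on libraries). In each of the other 7 tests 1 of 10 splits, the real one, reached its count. Over libraries the fit has a node term, and only 4 of the 10 splits part the libraries of every node; the other 6 keep the libraries of a node together in 2 of the 3 nodes, and they gave the highest other counts over libraries. Among the 4, the highest other split called 1 gene in B-like cells, 1 in CD4 T-like cells, 0 in CD8 T-like cells and 0 in all cells. The share is never under 0.25 for these 4 splits and never under 0.1 for 10, too few for a share under 0.05.

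The first pattern weighed is the 153 genes called in the same direction in B-like, CD4 T-like and CD8 T-like cells. Strain variants carried along with a genotype would sit in stretches of chromosome, and 57 of the 153 had another within 1 Mb, against a median of 36 in random draws and 50 at their upper bound, which is consistent with a strain variant for part of the genes; the labels give no strain background. An effect of the genotype on all cells was tested by how many of the genes differ within a genotype: 6.54% of the 153 (10 genes) differed at least 3-fold between tube sets of 1 genotype, against 0.346% of all genes (34 of 9832). That share passed the bound set against an effect of the genotype, yet 143 of the 153 did not differ so, and the bound judged all genes by these 10. After the result was seen it was therefore read as leaving this explanation open, and for the 143 genes a strain difference between the lines and an effect of the transgenes cannot be told apart.

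The second pattern is the lower interferon response in 5xFAD. For RNA from other cells, the test assumed that free RNA gives each class like levels. The median gene differed at least 1.89-fold between B-like and CD4 T-like cells in every library (1.89 to 2.55). Yet Hbb-bs, a red-cell globin, had 0.669 CPM in B-like and 7.58 CPM in CD4 T-like cells of iLN 5xFAD. RNA of red cells thus differed between classes, so the test cannot decide and RNA from other cells stays open. A tube set that stands apart stays open. The sets were matched in part by interferon genes, so leaving sets out is not independent of this pattern. With each of the 6 sets left out in turn, the median of the type I list ran from -0.68 to -0.20 in B-like, from -0.50 to -0.09 in CD4 T-like and from -0.40 to -0.11 in CD8 T-like cells, and the value nearest to 0 was -0.0851, without 5xFAD set 3 in CD4 T-like cells. An effect of the genotype itself, or of infection or housing that differed between cages, was not tested.

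The third pattern is the higher heat shock response in dCLN. Handling of the node before capture may contribute: the median ratio to iLN was above 0 in both genotypes in 9 of the 10 classes with enough cells, and in γδ or type 3 T-like cells it was 0.08 in WT and -0.03 in 5xFAD. A response spread over so many cell types would follow from handling, but also from the node's own tissue. For the explanation by 1 hashtag tube, all 3 dCLN tubes of WT lay above all iLN tubes in the 3 lymphocyte classes, but the lowest number was 1 tube, in B-like cells of 5xFAD, so it stays open there. The order in which nodes were handled is not in the labels, and a difference between the nodes stays open as untested.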

How the results depend on the processing

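The alternatives chosen after seeing the data were those by hashtag tube or matched tube set, the removal of cells without exactly 1 hashtag, and the list tests without antigen receptor genes. Libraries of a node were paired by the node term, and the fits on 18 tubes with the matched tube set as block rest on a match inferred from expression.

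Class shares kept their direction under every alternative run for B-like, CD4 T-like and CD8 T-like cells, with mean differences of -11.8 to -13.4, 9.24 to 10.0 and 9.73 to 9.91 percentage points. The dCLN difference of regulatory T-like cells was 0.129 with doublets kept. In the first deposit of the CD4 capture, doublets kept gave 70.6% CD4 T-like and 16.4% regulatory T-like cells, against 72.0% and 15.4%.

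The DESeq2 Wald test called fewer genes than edgeR in every contrast. It called 125, 41, 1 and 26 genes in B-like cells for genotype, dCLN against iLN, sCLN against iLN and dCLN against sCLN, 107, 39, 2 and 13 in CD4 T-like, 157, 37, 8 and 21 in CD8 T-like and 1926 by genotype over all cells. Without the node term the genotype counts were 503, 354, 483 and 198. Matched tube sets gave 42, 50, 55 and 0 (2074 at an unadjusted p under 0.05 by edgeR). With 18 tubes, B-like sCLN against iLN had 17 genes, CD4 T-like cells 17 for sCLN against iLN and 131 for dCLN against sCLN, and CD8 T-like cells 26 and 217. In CD4 T-like cells no filter gave 43 genes for sCLN against iLN and 130 for dCLN against sCLN, doublets kept and stricter quality limits gave 16 each for sCLN against iLN, and Leiden resolution 2.0 gave 956 by genotype and 159 for dCLN against sCLN. The cause was not tested.

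Leaving out 1 library, or 1 node's pair for the genotype, gave 470 to 1005, 91 to 423, 41 to 116 and 109 to 214 genes in B-like cells in the order above, 266 to 412, 111 to 241, 9 to 52 and 22 to 121 in CD4 T-like, 548 to 715, 104 to 379, 15 to 75 and 76 to 190 in CD8 T-like, and 2743 to 3590 over all cells.

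Camera called 129 lists, and 0 with an estimated correlation, where 2 residual degrees of freedom left hardly any list able to pass. With DESeq2 size factors 2 of these calls were lost and 1 gained, by tube 23 were lost and 22 gained, and without antigen receptor genes 4 were lost and 1 gained. Cells thinned to 1500 UMIs gave type I interferon medians of -0.22 in iLN B-like and -0.31 in dCLN CD8 T-like cells, and the interferon-γ median of sCLN CD4 T-like cells reversed to -0.00833.

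In CD4 T-like cells Ccr8 reversed to 0.15 for dCLN against iLN with doublets kept. S100a6 reversed for dCLN against sCLN to 0.55 under stricter quality limits and 0.26 with doublets kept. For sCLN against iLN, Ahnak reversed to 0.021 and Cd8a to 0.094 under stricter limits and Ccl5 to 0.074 with doublets kept. The cause was not tested. Of the named genes still tested, 63 kept their call and 190 lost it with the DESeq2 Wald test, 247 and 6 with size factors, 197 and 36 at Leiden resolution 2.0 and, for the genotype, 8 and 51 by matched tube set.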

Other observations

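The mixed library held 33.1% B-like, 18.1% CD4 T-like, 24.8% CD8 T-like and 3.44% germinal centre B-like cells, and Gm42418 took 0.786% of its UMIs. Its cells carried 4 hashtags that the labels link to no node or genotype.

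At a finer resolution, 84 plasma cell-like cells were found in dCLN WT, 43 in dCLN 5xFAD, 59 in sCLN WT, 17 in sCLN 5xFAD, 8 and 7 in iLN and 128 in the mixed library. Of their heavy chain UMIs, Ighg2b took 48.6% and Ighg2c 35.4% in dCLN WT, and Igha took 84.2% in dCLN 5xFAD. In sCLN WT Igha took 42.8% and Ighm 40.3%, and in sCLN 5xFAD Ighm took 97.2%. No test was made on so few cells.

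Endothelium-like cells numbered 31 in dCLN WT and 15 in dCLN 5xFAD and at most 1 in each other node library. By tube set in dCLN, they were 1.05% of cells in WT set 1 and 0 in the other WT sets. A cluster with both regulatory T cell and B cell markers held 0.942% of dCLN WT cells and at most 0.159% of any other library. In the CD4 capture, follicular helper-like cells made up 2.71%, 5.12%, 0.419% and 6.44% of tubes 1 to 4.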
